A study of Mus musculus with 40 samples.

How the data were processed

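The series holds total RNA from mouse CD4 T cells on Illumina MouseWG-6 v2 bead arrays. Per the labels, naive CD4+CD62L+ T cells were taken from lymph nodes and spleens of C57BL6 mice aged 8 to 12 weeks, WT or Malt1-/-, and induced to become Th1 or Th17 cells for 48 h or 72 h. RNA was extracted with Trizol, cleaned and treated with DNase I, checked on a Bioanalyser and turned into biotinylated cDNA. The 40 arrays fall into 8 groups of 5 by genotype, lineage and time, as the labels state, and no array was left out of the comparisons. How the cultures were stimulated, and which software read the arrays, is not given in the sources used here.

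The deposited raw values are intensity, the bead-summarised signal of each probe without background subtraction or scaling between arrays, since array minima and medians differ. The deposited detection column holds, per the file headers and as deposited, 1 minus the detection p-value of each probe, which on this platform compares the probe with the negative controls of its array. It rises with the signal of the same array. The value table of the authors is in log2 units. It was checked against the raw signals: it equals the log2 of the quantile-normalised raw signals centred on the median of each probe over the 40 arrays, with a largest absolute difference of 0.0149. Because it is centred on each probe, it carries no level, and the raw signals were used as the starting point.

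Signals were background-corrected with the normal and exponential model that uses the detection p-values, raised by an offset of 16, quantile normalised and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). Probes were kept when the detection p was under 0.05 on at least 5 of the 40 arrays, without regard to group, which left 20739 of 45281. Probes were named by the platform's gene table, in which 34885 had 1 gene symbol, 18 had several and 10378 were not listed. For each gene the kept probe with the highest mean over all arrays was used, which gave 10730 genes, 4274 of which had more than 1 kept probe. Another 3569 kept probes without 1 gene symbol were fitted separately. A gene detected on 0 of 5 arrays of a group is given as at least a number of times higher or lower, computed against a mean in which each signal of that group below the detection floor of its array, the lowest signal detected on it, was raised to that floor.

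Linear models were fitted with limma, with 1 mean for each of the 8 groups in a single fit of the 40 arrays and moderated variances (eBayes). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 10730 genes of a comparison. There were 16 comparisons: Malt1-/- minus WT in each lineage and time (4), the difference of that effect between lineages at each time (2) and between times in each lineage (2), Th17 minus Th1 in each genotype and time (4), and 72 h minus 48 h in each genotype and lineage (4). Comparisons that share arrays are not independent. The genotype comparisons share no arrays, but they share the variance of each gene from the single fit, so genes of low spread can be called in several of them. The overlap of genes called in pairs of genotype comparisons was tested with Fisher's exact test, two-sided, with adjustment over the 12 tests, leaving out Malt1. Replicate numbers showed no common pairing of arrays of different groups. Over 140 pairs of arrays with the same number, the median correlation of their residuals was 0.0140 (highest 0.513), and 11 of the 40 arrays correlated best with arrays of their own number. The 48 h and 72 h arrays of WT Th17 replicate 5 were closest to each other (correlation 0.989), as were those of Malt1-/- Th1 replicate 2 (0.988). So were WT Th1 48 h replicate 1 and 72 h replicate 4, whose numbers differ (0.988). A pairing of some arrays over time stays open, and the tests treated all arrays as independent.

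The groups, filter, probe rule, tests, gene lists, alternatives and rule for named genes were fixed before the data were examined. Genes named in the text were Malt1, the 8 largest rises and falls of each genotype comparison among called genes whose 5 Malt1-/- values all lay on the same side of the 5 WT values, a fixed set of T cell genes (among them Il17a, Il17f, Il21, Il22, Il23r, Csf2, Ifng, Tbx21, Il2, Foxp3, Gata3, Rel, Relb, Nfkb2, Tnfaip3, Icos, Tnfrsf4, Ctla4 and Zc3h12a), up to 4 members of each list with the smallest p, and the 5 largest called rises and falls of every other comparison. The text describes the part of these that carries each comparison. The 16 genes called in all genotype comparisons were singled out after their values were seen. Il22 and Il23r did not pass the filter, and 1 gene of the set is not reported here.

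The 31 gene lists were pathways and programmes (Th17 programme, pathogenic Th17, non-pathogenic Th17, Th1 programme, Th2 programme, Treg programme, Tfh programme, helper cytokines, chemokines, NF-kappaB pathway and targets, T cell receptor signalling, MALT1 substrates, Regnase-1 and Roquin target mRNAs, T cell activation, naive T cell, cell cycle, glycolysis, apoptosis, interferon response, TGF-beta response, STAT3 and STAT5 response, cholesterol synthesis, unfolded protein and integrated stress response, ribosome and cytotoxic) and markers of other cells (B cell, myeloid, CD8 T cell, NK cell, gamma-delta T cell and erythroid). Lists share genes, so their calls are not independent. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison, and members were counted past the adjusted p over all genes and adjusted over the list alone. Camera compares the genes of a list with all other genes, whereas fry tests them alone.

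The code was tested on simulated data. Of 50 changes planted in each genotype comparison, from 14 to 18 were found at 1.5-fold, from 37 to 42 at 2-fold and from 47 to 49 at 3-fold, and a planted fall of the glycolysis list was found while 0 of the other lists were called. The simulated genes varied independently of each other, and no simulated array stood apart. These rates therefore do not cover correlated genes or deviant arrays, and say nothing of false list calls in the real data. The precision of each value is limited by the 5 arrays of a group.

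The alternatives were no background correction, median scaling in place of quantile normalization, the value table of the authors, no detection filter, a stricter filter (detection p under 0.01 on at least 20 arrays), a fit of the compared groups alone, the replicate number as a block (replicate block), an intensity trend with robust variances and leaving out each array in turn. Leaving out the 8 arrays that lay closer to the mean of another group was added after seeing the data. A block by chip could not be used, since the files name no chips. For each comparison 100 splits of its arrays were counted. Single values were compared with exact permutation tests, two-sided, for which 5 arrays against 5 give a p of at least 0.00794.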

Results

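The series measured messenger RNA in mouse CD4 T cells with bead arrays. Lymph nodes and spleens of C57BL6 mice, either wild type (WT) or lacking Malt1 (Malt1-/-), had given naive T cells positive for CD4 and CD62L. These had been induced to become Th1 or Th17 cells. Th1 and Th17 cells are helper T cells that make interferon gamma and interleukin 17, respectively. Malt1 encodes a scaffold and protease that links the antigen receptors of lymphocytes to NF-kappaB, a family of transcription factors. RNA was taken 48 h or 72 h after induction, which gave 8 groups of 5 arrays each, 40 arrays in all. Each array held 45281 probes, of which 14640 to 17409 per array were detected above background. The median raw signal ran from 127.1 to 193.3 and the 95th percentile from 1099.7 to 2517.4. Differences are on the log2 scale with the standard error (SE) of the fit, levels are group means on the log2 scale with their SD, and n is 5 arrays per group throughout. The number of arrays limits the precision. The labels do not say that the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical.

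**Figure D1:**
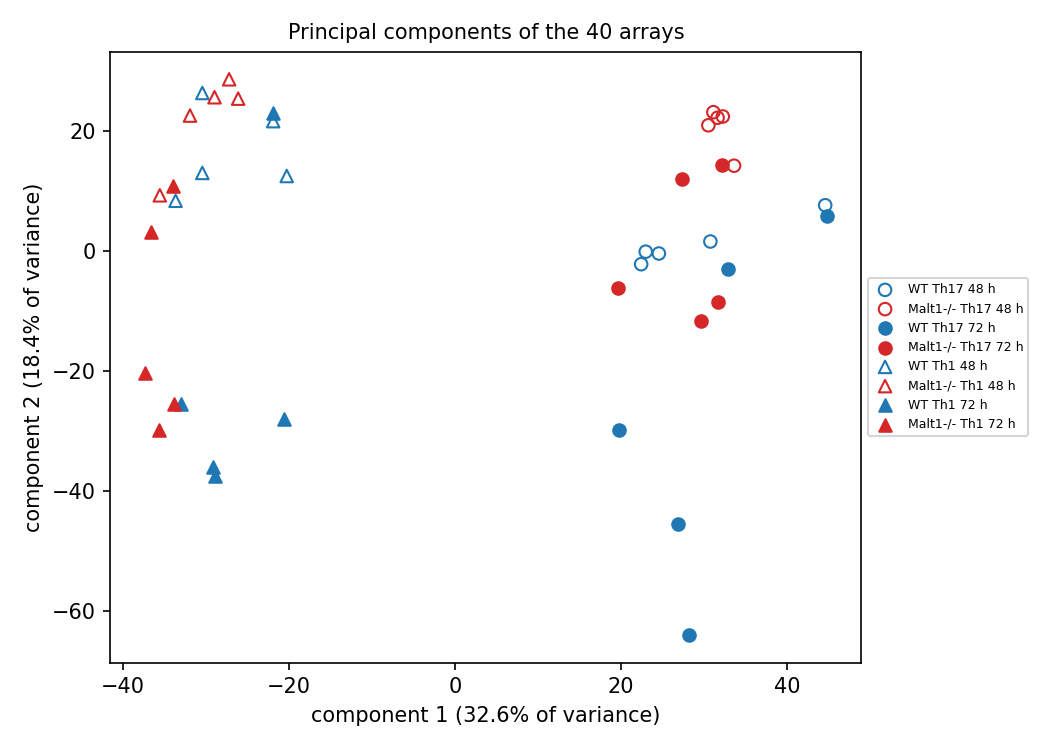
Each point is 1 of the 40 arrays, placed by its first and second principal component over the tested genes (axes in log2 units, with the percent of variance). Red is Malt1-/- and blue WT, circles are Th17 and triangles Th1, and open symbols are 48 h and filled symbols 72 h. The first component, with 32.6% of the variance, parts Th17 from Th1 arrays, and the second holds 18.4%.

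Malt1 itself was lower in Malt1-/- cells in every comparison. Its probe (ILMN_1216818) was 14.4-fold lower in Th17 cells at 48 h, 26.9-fold lower in Th17 cells at 72 h, 17.2-fold lower in Th1 cells at 48 h and 30.2-fold lower in Th1 cells at 72 h. The log2 differences were -3.85, -4.75, -4.10 and -4.92, each with an SE of 0.30 and n = 5 per group, and the highest of the adjusted p-values was 3.2e-11. The Malt1-/- levels of 8.64 ± 0.39, 7.93 ± 0.57, 6.70 ± 0.42 and 6.50 ± 0.56 stayed above background on all arrays, while WT levels were 12.49 ± 0.39, 12.68 ± 0.32, 10.80 ± 0.57 and 11.42 ± 0.60. The labels do not say which part of the gene is missing, and a second Malt1 probe (ILMN_2419951) lay near background in every group.

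**Figure D2:**
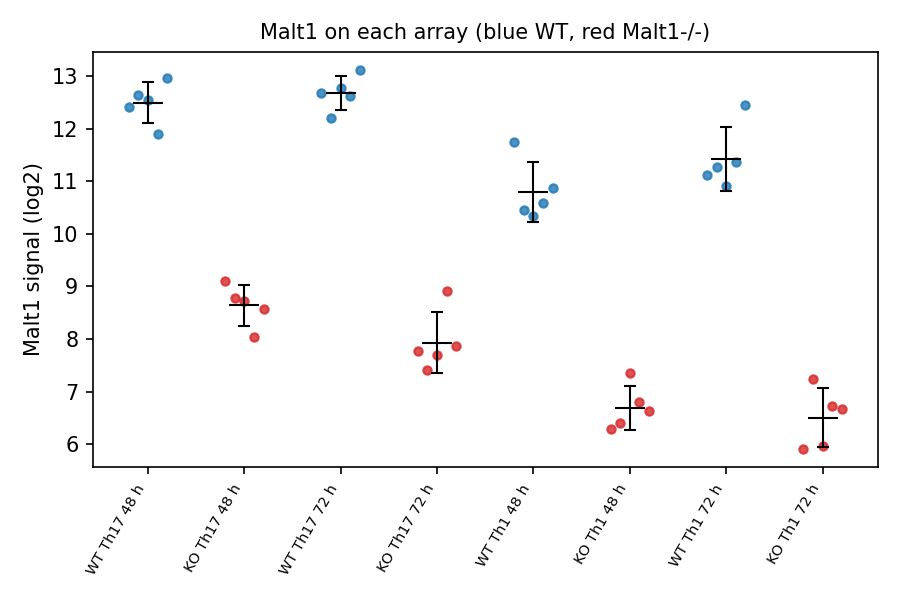
Malt1 signal (log2, vertical axis) in each of the 8 groups (horizontal axis); each point is 1 array, and bars give the mean ± SD of 5 arrays. Every Malt1-/- group lies below its WT group, by -3.85 to -4.92.

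In Th17 cells at 48 h, loss of Malt1 lowered the cytokines that define the lineage and a set of others. Il17a was 7.22-fold lower (log2 difference -2.85 ± 0.49 SE, level 7.83 ± 1.36 against 10.68 ± 0.72 in WT, n = 5 per group, adjusted p = 0.00093). Without Malt1-/- replicate 1, which stood apart, the log2 difference was -3.45. Il17f, the related Th17 cytokine, was 3.74-fold lower (-1.90 ± 0.49, adjusted p = 0.020). Il10, a cytokine that restrains inflammation, was 7.10-fold lower (-2.83 ± 0.61, adjusted p = 0.0063). Lif, a cytokine of the interleukin 6 family, was 5.02-fold lower (-2.33 ± 0.35, adjusted p = 0.00016), and Tnf 4.06-fold lower (-2.02 ± 0.45, adjusted p = 0.0082). Ctla4, an inhibitory receptor of activated T cells, fell by 1.66 on the log2 scale. Akr1c18, an enzyme that inactivates progesterone, was 14.2-fold higher (3.83 ± 0.96, level 12.02 ± 0.35 against 8.19 ± 1.80, adjusted p = 0.017). Pdcd1lg2, a ligand of the inhibitory receptor PD-1, rose by 1.72, and Wdfy1, an adaptor of Toll-like receptor signalling, rose by 2.08.

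Among the gene lists at 48 h in Th17 cells, glycolysis changed most: 8 of its 13 tested genes fell, none rose and the rest did not pass, with 12 falling when adjusted over the list alone. Its median difference was -0.72. Pfkp, a phosphofructokinase, fell by 1.39 ± 0.31 and Pkm, the last enzyme of the pathway, by 0.68 ± 0.16. Camera called the list lower (adjusted p = 4.3e-09), but the call was lost with an estimated correlation (adjusted p = 0.56 with an estimated correlation). Of 14 mRNAs that Regnase-1 or Roquin bind, RNases and RNA-binding proteins that MALT1 cleaves, 3 fell and 1 rose (7 and 1 when adjusted over the list alone; camera adjusted p = 0.017, and adjusted p = 0.56 with an estimated correlation). Those that fell were Ctla4, Tnf and Ier3, an immediate early gene, and Tnfsf4, the ligand of OX40, rose. Of 24 helper cytokines 5 fell and 1 rose (6 and 2 when adjusted over the list alone; camera adjusted p = 0.087). In the NF-kappaB list of 29 genes, 4 rose and 2 fell (4 and 5 when adjusted over the list alone). The risers included the NF-kappaB subunits Nfkb2 (1.11 ± 0.21) and Rela (0.67 ± 0.15) and the apoptosis inhibitor Birc3 (1.51 ± 0.35), while Rel, Relb and Tnfaip3 had differences of 0.17, -0.17 and 0.25 and did not pass. Camera saw no common direction in that list (adjusted p = 0.83), whereas fry found change in either direction (adjusted p = 9.0e-07). In the cholesterol synthesis list 3 of 9 genes fell and none rose (4 fell and 1 rose when adjusted over the list alone; camera adjusted p = 0.13). Gata3, the transcription factor of Th2 cells, rose by 1.77 ± 0.36 (adjusted p = 0.0035), though only 1 of 5 WT arrays detected it and the call was lost without background correction (adjusted p = 0.061). Beside these groups, the myeloid marker S100a8 was at least 3.16-fold higher, detected on 3 of 5 Malt1-/- and 0 of 5 WT arrays (adjusted p = 0.028), as 1 of 7 tested myeloid markers to rise (2 when adjusted over the list alone).

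Over all genes in Th17 cells at 48 h, 685 of 10730 passed (366 higher and 319 lower), 137 of them at least 2-fold higher and 72 at least 2-fold lower. Among genes chosen before the data were examined, Il2 (-2.31, adjusted p = 0.070), Ifng (1.22), Il21 (0.38), Csf2 (0.45), Tbx21 (-0.26), Icos (-0.67), Tnfrsf4 (-0.40) and Zc3h12a (-0.14) did not pass, and Il22 and Il23r were not detected on enough arrays to be tested. The other kept Ifng probe did pass (1.59, adjusted p = 0.018 over all kept probes). Malt1-/- replicate 1 stood apart in Il2 (9.87 against 6.41 to 7.32 in the others of its group), Ifng (6.35 against 7.88 to 8.34) and Tnfrsf4 (13.52 against 12.88 to 13.02). Median scaling in place of quantile normalization moved the median of all genes by 0.17 on the log2 scale and the share of higher genes from 53.4% to 93.1%. It ended the calls of Pkm and Fdps (farnesyl diphosphate synthase, -0.73 ± 0.13) but not of Pfkp, Il17a or Il17f. The count followed each array. It was 281, 383, 307, 411 and 1156 without WT replicates 1 to 5 in turn and 364, 307, 312, 401 and 348 without Malt1-/- replicates 1 to 5. It was 1651 without the 8 arrays that lay closer to another group. S100a8 lost its call without WT replicate 1, 2 or 3 or Malt1-/- replicate 1 or 5 (adjusted p up to 0.11).

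**Figure D3:**
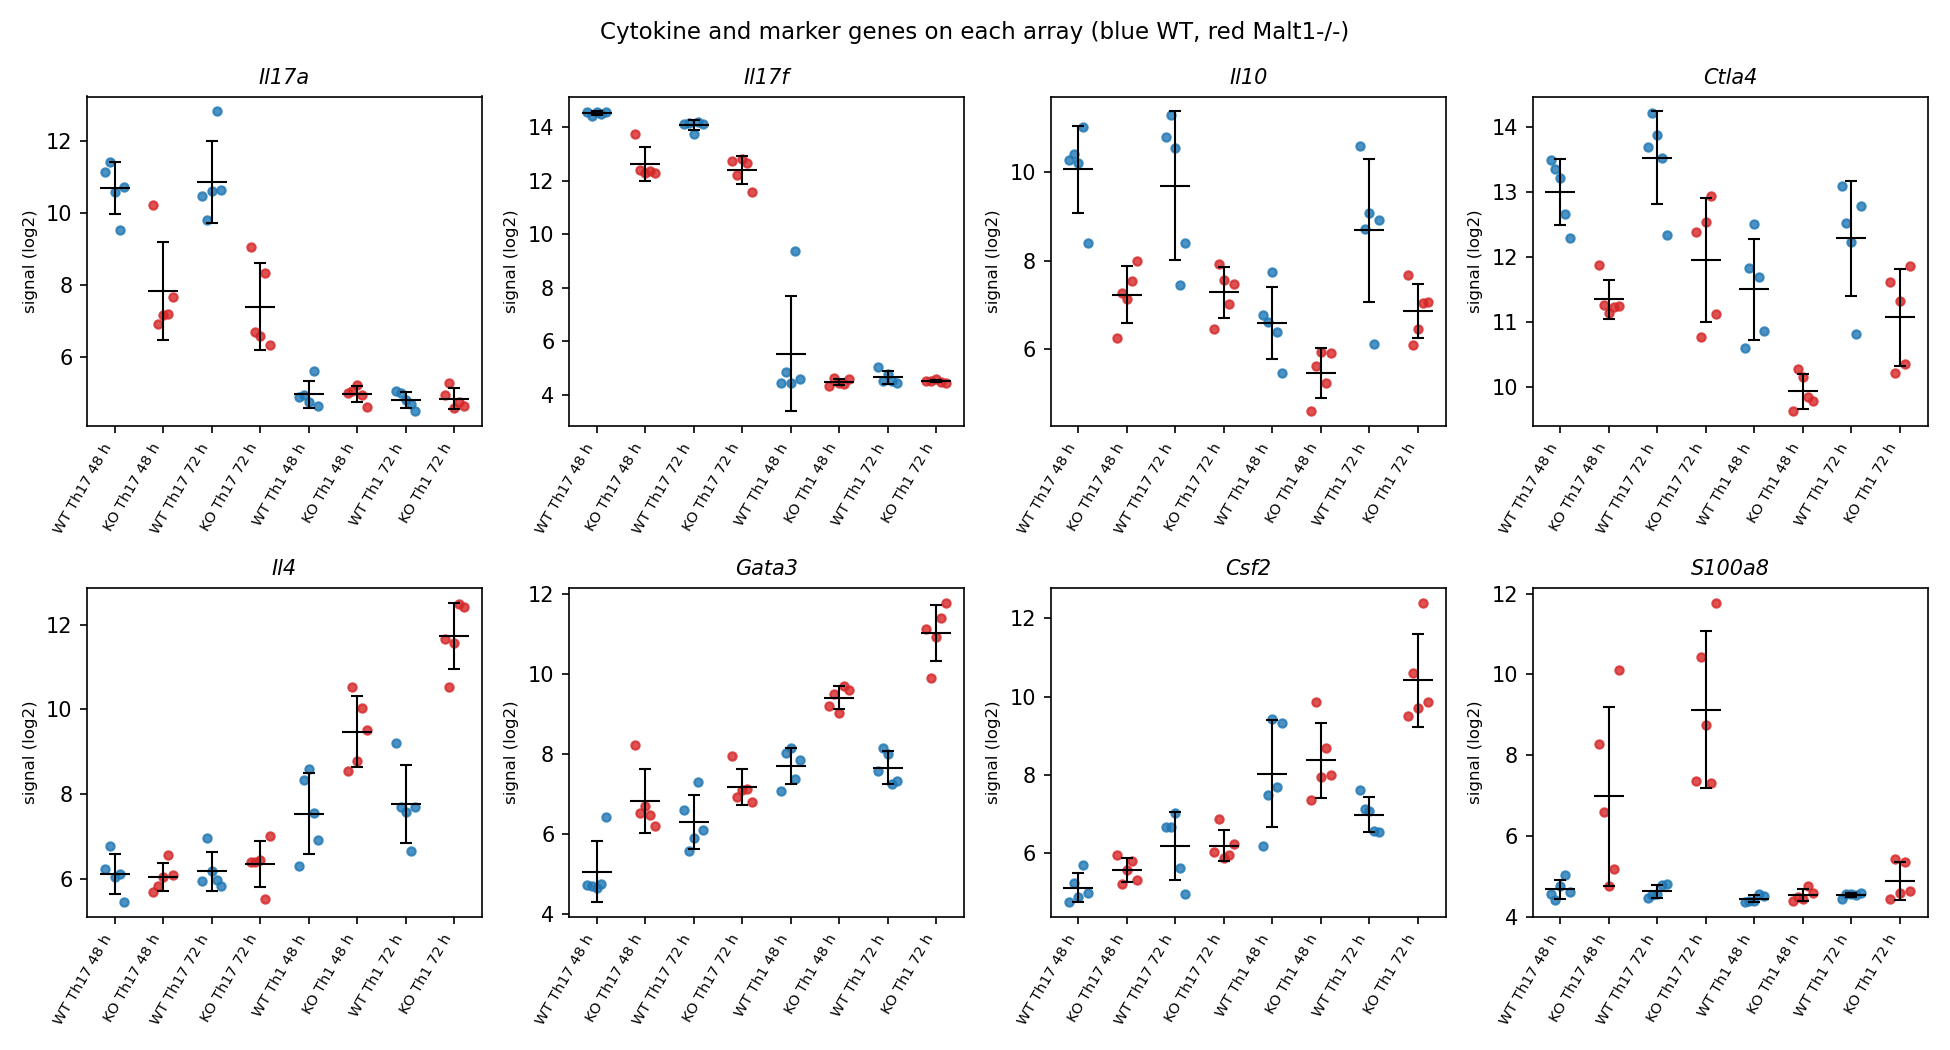
Signal (log2, vertical axes) of 8 genes in each of the 8 groups (horizontal axes); each point is 1 array, bars give the mean ± SD of 5 arrays, and KO is Malt1-/-. Il17a was lower in Malt1-/- Th17 cells by -2.85 at 48 h and -3.46 at 72 h, and Il4 was higher in Malt1-/- Th1 cells by 1.94 and 3.96.

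In Th17 cells at 72 h, Il17a was lower in Malt1-/- cells by -3.46 ± 0.49 (level 7.40 ± 1.21 against 10.86 ± 1.14, n = 5 per group, adjusted p = 2.0e-05). Icos, a costimulatory receptor, fell by 1.37 ± 0.24 (adjusted p = 0.00065), and Lif fell by 1.74 ± 0.35 (adjusted p = 0.0041). Higher genes included S100a8 and S100a9, the subunits of calprotectin, which is abundant in neutrophils and monocytes. S100a8 was at least 14.8-fold higher and S100a9 at least 6.44-fold higher, both detected on 5 of 5 Malt1-/- and 0 of 5 WT arrays (adjusted p = 1.8e-05 and 0.00012). Ubd, a ubiquitin-like protein (2.44 ± 0.35), Sphk1, which makes sphingosine 1-phosphate (2.37 ± 0.33), and Atp1b1, a subunit of the sodium pump (2.67 ± 0.36), also rose.

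Of 24 cell cycle genes 11 rose in Th17 cells at 72 h, none fell and the rest did not pass, with 14 rising when adjusted over the list alone (median 0.49; camera adjusted p = 4.1e-08, a call lost with an estimated correlation, adjusted p = 0.069). Examples were Tyms, which makes thymidylate (1.03 ± 0.21), Cdc20, an activator of the anaphase complex (0.72 ± 0.15), and Mcm4, a helicase subunit (0.48). Myeloid markers moved the same way: 4 of 7 rose (S100a8, S100a9, Lyz1 and Fcer1g), or 5 when adjusted over the list alone (camera adjusted p = 0.00029, and adjusted p = 0.069 with an estimated correlation). In the Th17 programme 2 of 14 genes fell, Il17a and Il17f, and none rose (3 fell when adjusted over the list alone; camera adjusted p = 0.0012, and adjusted p = 0.069 with an estimated correlation). Regnase-1 and Roquin targets fell in 4 of 14 cases and rose in 1 (8 and 1 when adjusted over the list alone; camera adjusted p = 0.00029, and adjusted p = 0.069 with an estimated correlation). Helper cytokines fell in 6 of 24 cases and rose in none (7 fell and 2 rose when adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.43 with an estimated correlation). The naive T cell list was called lower with 1 of 11 genes falling (3 when adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.28 with an estimated correlation). The glycolysis list was called lower with 0 of 13 genes passing (median -0.34; camera adjusted p = 0.011, and adjusted p = 0.57 with an estimated correlation). In the NF-kappaB list 3 of 29 genes rose, Nfkb2 (1.01 ± 0.21) among them, and 2 fell (6 and 7 when adjusted over the list alone; camera adjusted p = 0.91). Cd8b1, a marker of CD8 T cells, fell by 0.65.

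Over all genes in Th17 cells at 72 h, 474 passed (310 higher and 164 lower), 79 of them at least 2-fold higher and 69 at least 2-fold lower. Il17f (-1.67 ± 0.49, adjusted p = 0.044) lost its call without WT replicate 1, 2, 3 or 4 or Malt1-/- replicate 1, 2 or 5 (adjusted p up to 0.13), with median scaling (adjusted p = 0.099) and with no detection filter (adjusted p = 0.070). Ctla4 (-1.58) and Cd8b1 lost theirs without WT replicate 1 or 3 or Malt1-/- replicate 2 or 5 (adjusted p up to 0.10). Mcm4 lost its call without WT replicate 3 or Malt1-/- replicate 5 (adjusted p up to 0.10), and Fcer1g without WT replicate 1 or 3 or Malt1-/- replicate 2, 3 or 5 (adjusted p up to 0.26). Gata3 (0.89), Ifng (1.55, adjusted p = 0.052), Il2 (-0.67), Tnfrsf4 (-0.58), Csf2 (0.01), Tbx21 (0.02), Il21 (0.09), Rel (0.43), Relb (0.16), Tnfaip3 (-0.26) and Zc3h12a (-0.37) did not pass. The other kept Ifng probe did pass (1.90, adjusted p = 0.0053 over all kept probes). The count was 179 without WT replicate 1, 105 without WT replicate 3, 740 without WT replicate 4, 846 without WT replicate 5, 152 without Malt1-/- replicate 2 and 136 without Malt1-/- replicate 5. It was 131 with median scaling, 58 with only these 10 arrays in the fit and 1685 without the 8 arrays closer to another group. With only these 10 arrays Icos, Lif, Lyz1, S100a9, Tyms and Cdc20 lost their calls. The helper cytokine call was lost without WT replicate 2 (adjusted p = 0.098) or Malt1-/- replicate 4 (adjusted p = 0.053). The glycolysis call was lost without WT replicate 1 or 2 or Malt1-/- replicate 2 or 5 (adjusted p up to 0.36).

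In Th1 cells at 48 h, loss of Malt1 raised genes of the Th2 programme, a helper lineage that makes interleukin 4. Il4 was 3.83-fold higher (1.94 ± 0.42, level 9.48 ± 0.83 against 7.54 ± 0.95, n = 5 per group, adjusted p = 0.0090) and Gata3 3.27-fold higher (1.71 ± 0.36, 9.41 ± 0.29 against 7.70 ± 0.45, adjusted p = 0.0068). Ccr4, a chemokine receptor of Th2 cells, was at least 1.52-fold higher, detected on 5 of 5 Malt1-/- and 0 of 5 WT arrays (adjusted p = 0.012). Il21, a cytokine that helps B cells, was 4.56-fold higher (2.19 ± 0.42, adjusted p = 0.0031), and the peptide genes Edn1 (endothelin 1) and Nts (neurotensin) moved apart, by 2.29 ± 0.38 and -2.29 ± 0.23. Dhcr7, the last enzyme of cholesterol synthesis, fell by 1.37 ± 0.24, and Ccr7, a receptor that guides T cells to lymph nodes, by 1.33 ± 0.30.

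The Th2 list rose in 3 of 8 genes, none fell and the rest did not pass (4 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.00057, and adjusted p = 0.086 with an estimated correlation). Regnase-1 and Roquin targets were called lower with 1 of 14 falling, Ctla4 (6 fell and 1 rose when adjusted over the list alone; camera adjusted p = 0.00028, and adjusted p = 0.086 with an estimated correlation). Helper cytokines rose in 3 of 24 cases, Il4, Il21 and Tnfsf8, and fell in none (4 and 3 when adjusted over the list alone; camera adjusted p = 0.60; fry for change in either direction, adjusted p = 0.0011). The cholesterol synthesis list was called lower with Dhcr7 as the 1 of 9 genes to fall (2 when adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.23 with an estimated correlation). The unfolded protein and integrated stress response list was called lower with 0 of 14 genes passing (2 when adjusted over the list alone; camera adjusted p = 0.0034, and adjusted p = 0.51 with an estimated correlation). The glycolysis list was also called lower with no gene passing (camera adjusted p = 0.018, and adjusted p = 0.59 with an estimated correlation). So were the B cell markers (camera adjusted p = 0.030, and adjusted p = 0.56 with an estimated correlation). The T cell receptor signalling list was called higher in the same way (camera adjusted p = 0.030, and adjusted p = 0.40 with an estimated correlation). In the NF-kappaB list 1 of 29 genes rose, Rela, and none fell (4 and 3 when adjusted over the list alone; camera adjusted p = 0.93). Of the Th1 programme 0 of 15 genes passed, with Ifng at -0.94 (adjusted p = 0.42) and Tbx21, the Th1 transcription factor, at 0.14.

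Over all genes in Th1 cells at 48 h, 149 passed (84 higher and 65 lower), 36 of them at least 2-fold higher and 33 at least 2-fold lower. Il2 (-0.73), Csf2 (0.35), Nfkb2 (0.78), Rel (-0.62), Icos (-0.65), Zc3h12a (-0.39) and Tnfaip3 (-0.17) did not pass, and Il17a and Il17f were detected on no array but WT replicate 4 (5.61 and 9.37). The count was 93 without WT replicate 2, 84 without WT replicate 5, 97 without Malt1-/- replicate 5, 62 with median scaling and 350 without the 8 arrays closer to another group. Il4 lost its call with only these 10 arrays in the fit, Ccr4 and Rela with median scaling, and Ccr7 without WT replicate 5 (adjusted p = 0.066). The stress response call was lost without WT replicate 3 (adjusted p = 0.069). The glycolysis call was lost without WT replicate 3 (adjusted p = 0.076) or Malt1-/- replicate 3 (adjusted p = 0.084), and the B cell call was lost without WT replicate 3 (adjusted p = 0.50), Malt1-/- replicate 1 (adjusted p = 0.089) or Malt1-/- replicate 2 (adjusted p = 0.052). No background correction, the value table of the authors, the stricter filter and leaving out the 8 arrays also ended the B cell call. With fry the stress response, glycolysis, B cell and T cell receptor signalling calls were lost. The T cell receptor signalling call was lost without WT replicate 2, 3 or 4 or Malt1-/- replicate 3 or 4 (adjusted p up to 0.12) and with no detection filter (adjusted p = 0.083).

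In Th1 cells at 72 h Th2 genes were higher without Malt1, although the change from 48 h did not pass for Il4 (2.02, adjusted p = 0.33), Gata3 (1.65, adjusted p = 0.42) or Il13 (1.11, adjusted p = 0.38). Il4 was 15.6-fold higher in Malt1-/- cells (3.96 ± 0.42, level 11.73 ± 0.79 against 7.77 ± 0.92, n = 5 per group, adjusted p = 2.6e-08), and Gata3 was 10.3-fold higher (3.36 ± 0.36, 11.03 ± 0.71 against 7.67 ± 0.40, adjusted p = 3.2e-08). Il13, another Th2 cytokine, was 2.45-fold higher (1.29 ± 0.24), and Ccr8, a chemokine receptor found on Th2 cells, was 5.65-fold higher (2.50 ± 0.49). Csf2, which encodes the growth factor GM-CSF, was 10.9-fold higher (3.44 ± 0.50, 10.42 ± 1.18 against 6.98 ± 0.45, adjusted p = 1.4e-05). Akr1c18 (5.12 ± 0.96), the zinc finger gene Osr2 (4.43 ± 0.38), Edn1 (3.73 ± 0.38) and Scin, an actin-severing protein (3.55 ± 0.33), rose as well, and Tnf was 4.01-fold lower (-2.00 ± 0.45, adjusted p = 0.0082).

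The Th2 list rose in 5 of 8 genes and fell in none, with 7 rising when adjusted over the list alone (median 1.44; camera adjusted p = 1.8e-12), and this call held with an estimated correlation (adjusted p = 5.4e-05 with an estimated correlation). It was the only list call of the 4 genotype comparisons to do so. Helper cytokines rose in 5 of 24 cases (Il4, Csf2, Il13, Tnfsf8 and Il21) and fell in 1, Tnf (8 and 3 when adjusted over the list alone; camera adjusted p = 0.021, and adjusted p = 0.47 with an estimated correlation). Regnase-1 and Roquin targets fell in 3 of 14 cases, Tnf, Nfkbiz and Nfkbid, and rose in 1, Tnfsf4 (6 and 1 when adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.34 with an estimated correlation). The cholesterol synthesis list was called lower with 1 of 9 genes falling (2 when adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.34 with an estimated correlation). In the NF-kappaB list 4 of 29 genes fell, among them the atypical inhibitors Nfkbiz (-1.47 ± 0.27) and Nfkbid (-0.91 ± 0.22), and 2 rose (4 and 2 when adjusted over the list alone; camera adjusted p = 0.93; fry for change in either direction, adjusted p = 3.3e-06). Bcl2l11, a death-promoting gene, fell by 1.47 ± 0.31. None of the 15 Th1 programme genes passed in limma, of which Ifng differed by -0.13 and Tbx21 by 0.28.

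Over all genes in Th1 cells at 72 h, 297 passed (198 higher and 99 lower), 90 of them at least 2-fold higher and 31 at least 2-fold lower. Il21 (1.59, adjusted p = 0.030) lost its call without WT replicate 2, 3 or 4 or Malt1-/- replicate 1, 4 or 5 (adjusted p up to 0.086) and with no detection filter (adjusted p = 0.053). Il2 (0.89), Ctla4 (-1.22, adjusted p = 0.11), Icos (-0.64), Zc3h12a (-0.55) and Tnfaip3 (0.74) did not pass. The count was 138 without WT replicate 2, 170 without WT replicate 3, 607 without WT replicate 4, and 196 without Malt1-/- replicate 4. It was 141 with median scaling, 82 with only these 10 arrays in the fit and 553 without the 8 arrays closer to another group. With only these 10 arrays Il13, Ccr8 and Nfkbid lost their calls. The helper cytokine call was lost without WT replicate 4 (adjusted p = 0.28) or Malt1-/- replicate 4 (adjusted p = 0.052). The Regnase-1 and Roquin call was lost without WT replicate 1 (adjusted p = 0.10) and the cholesterol call without WT replicate 4 (adjusted p = 0.12) or Malt1-/- replicate 1 (adjusted p = 0.10).

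**Figure D4:**
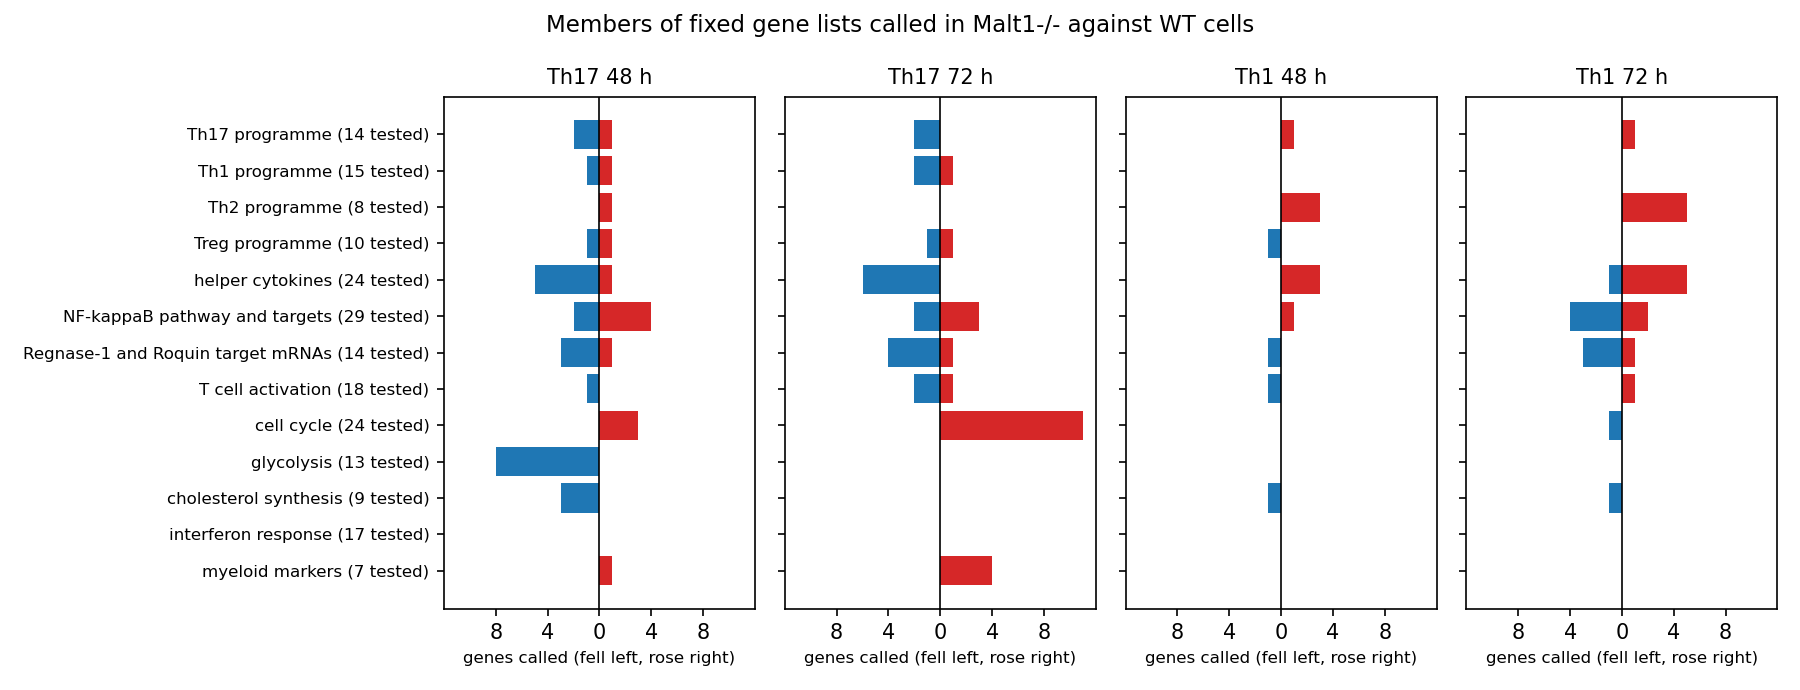
Number of members (horizontal axis, genes) of 13 of the gene lists (vertical axis, with the number tested) that were called higher (red, to the right) or lower (blue, to the left) in Malt1-/- cells in the 4 genotype comparisons. The longest bars are cell cycle in Th17 cells at 72 h (11 of 24 higher) and glycolysis in Th17 cells at 48 h (8 of 13 lower).

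The remaining lists had no camera call in any of the 4 genotype comparisons. Across these comparisons the adjusted p of camera ran from 0.12 to 0.90 for pathogenic Th17 genes, from 0.12 to 0.32 for non-pathogenic Th17 genes, from 0.12 to 0.91 for the Th1 programme, from 0.060 to 0.98 for the Treg programme and from 0.24 to 0.60 for the Tfh programme. It ran from 0.079 to 0.63 for chemokines, from 0.58 to 0.98 for MALT1 substrates, and from 0.24 to 0.89 for T cell activation. For apoptosis it ran from 0.17 to 0.70, from 0.17 to 0.83 for the interferon response, from 0.24 to 0.98 for the TGF-beta response and from 0.099 to 0.89 for the STAT3 and STAT5 response. The ribosome list (0.20 to 0.81), cytotoxic genes (0.17 to 0.98), NK cell markers (0.27 to 0.50) and gamma-delta T cell markers (0.71 to 0.93) had none either, and 1 gene each could be tested for CD8 T cell and erythroid markers. Among the pathogenic Th17 genes in Th17 cells at 72 h the median was 0.13 and the mean 0.12 while camera pointed lower, and among TGF-beta response genes the median was -0.08 and the mean 0.18.

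Between the genotypes 16 genes differed the same way in all 4 comparisons, 11 higher and 5 lower. Besides Malt1, Ppic (cyclophilin C) was lower by -1.98, -2.05, -2.17 and -1.93 in Th17 cells at 48 h and 72 h and Th1 cells at 48 h and 72 h, and Entpd4, Tnfaip8 and Wdyhv1 were lower as well. Wdfy1 was higher by 2.08, 2.00, 2.62 and 2.81, and Igsf3 by 1.76, 1.82, 2.48 and 2.06. The others were Akr1c12, Bmp1, Casz1, Fndc10, Papss2, Rab4a, S1pr2, Srfbp1 and Tm4sf5. With Malt1 left out, Th1 cells at 48 h and 72 h shared 45 higher genes where 1.55 were expected (Fisher's exact test, two-sided, adjusted p = 4.3e-56), and Th17 cells at 48 h and 72 h shared 54 where 10.6 were expected (adjusted p = 2.6e-23). Between the lineages at 72 h, 36 higher genes were shared where 5.72 were expected (adjusted p = 1.1e-18). The expected counts and these p-values take no account of the shared variance of each gene or of correlation between genes. Across all genes, which are not independent replicates, the log2 differences correlated from 0.21 (Th17 at 48 h with Th1 at 72 h) to 0.50 (Th1 at 48 h with 72 h).

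The effect of Malt1 loss was then compared directly between Th17 and Th1 cells. At 72 h the Th2 genes parted the lineages. The effect on Il4 was lower in Th17 than in Th1 cells by -3.79 ± 0.59 (n = 5 per group, adjusted p = 0.00048), and on Gata3 by -2.48 ± 0.51 (adjusted p = 0.0084). It was lower on Csf2 by -3.43 ± 0.70 (adjusted p = 0.0084) and on Osr2 by -4.23 ± 0.54 (adjusted p = 3.2e-05). The effect on Il17a, which Th1 cells hardly expressed, differed by -3.49 ± 0.70 (adjusted p = 0.0070). S100a8 (4.15 ± 0.90), Lyz1 (2.43 ± 0.52, a fitted difference, since it was not detected in Th1 cells), Fscn1, an actin-bundling protein (2.81 ± 0.59), Kynu, an enzyme of tryptophan breakdown (2.52 ± 0.48), and the thymidine kinase Tk1 (1.01 ± 0.20) had the higher effect in Th17 cells. At 48 h Nts (2.26 ± 0.32), Gm4951 (1.80 ± 0.32) and Alpk2 (-2.52 ± 0.49) differed, the first because it fell in Th1 cells and was not detected in Th17 cells.

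By list, the difference between lineages at 72 h was lower for Th2 genes (3 of 8 fell and none rose, 6 fell when adjusted over the list alone; camera adjusted p = 5.2e-11). It was also lower for helper cytokines (4 of 24 fell and none rose, 8 fell and 1 rose when adjusted over the list alone; camera adjusted p = 1.4e-07) and lower for the Th17 programme (1 of 14 fell and none rose, 2 fell when adjusted over the list alone; camera adjusted p = 9.0e-05). It was higher for cell cycle genes (1 of 24 rose and none fell, 14 rose when adjusted over the list alone; camera adjusted p = 1.1e-11). The 1 that passed was Tk1, of whose 3 other kept probes none was called the same way and 2 had the opposite sign. These 4 calls held with an estimated correlation (adjusted p = 0.00019, 0.025, 0.020 and 0.019 with an estimated correlation). Myeloid markers moved with the cell cycle genes, with 3 of 7 higher and none lower (4 when adjusted over the list alone; camera adjusted p = 0.00092, and adjusted p = 0.11 with an estimated correlation). Other calls of camera at 72 h were lost. These were T cell receptor signalling lower (0.042, and adjusted p = 0.38 with an estimated correlation), and naive T cell lower (0.041, and adjusted p = 0.38 with an estimated correlation) and glycolysis lower (0.016, and adjusted p = 0.62 with an estimated correlation). They also included interferon response lower (0.0095, and adjusted p = 0.38 with an estimated correlation) and cholesterol synthesis higher (0.033, and adjusted p = 0.36 with an estimated correlation). At 48 h the glycolysis list alone was called lower (0 of 13 genes; camera adjusted p = 0.0019, and adjusted p = 0.64 with an estimated correlation).

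In all, 75 genes differed between lineages at 72 h (34 higher and 41 lower in Th17) and 15 at 48 h (8 higher and 7 lower). The count at 72 h was 44 without Malt1-/- Th1 replicate 5, 36 with median scaling and 27 with only these 20 arrays in the fit. It was 347 without the 8 arrays closer to another group, where Il17a lost its call (-2.60, adjusted p = 0.064). S100a8 lost its call without background correction. The list calls lost with an estimated correlation at 72 h, apart from the myeloid call, were each also lost in 2 to 11 of the 20 fits that left out 1 array (adjusted p up to 0.34). The count at 48 h was 7 without WT Th17 replicate 1, WT Th1 replicate 3 or WT Th1 replicate 5, 68 without WT Th17 replicate 5, and 9 without Malt1-/- Th17 replicate 2. It was 42 without WT Th1 replicate 1, 26 without WT Th1 replicate 2, and 8 without Malt1-/- Th1 replicate 1 or 4. It was 76 with only these 20 arrays in the fit and 181 without the 8 arrays.

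Between 48 h and 72 h, the difference between the genotypes in Th1 cells moved upward for Ccr8 (3.71 ± 0.70, n = 5 per group, adjusted p = 0.0093), Scin (3.50 ± 0.46, adjusted p = 6.9e-05), the ephrin Efna5 (2.35 ± 0.44) and the linker histone H1f2 (1.69 ± 0.28). For Ccr8 it went from -1.21 at 48 h, which did not pass, to 2.50 at 72 h. In all 8 genes passed (6 higher and 2 lower). The Th2 list was higher, with 1 of 8 genes rising and none falling (4 when adjusted over the list alone; camera adjusted p = 0.00011), and this call held with an estimated correlation (adjusted p = 0.032 with an estimated correlation). Camera also called helper cytokines (0.00088, and adjusted p = 0.24 with an estimated correlation) and pathogenic Th17 genes (0.011, and adjusted p = 0.14 with an estimated correlation). Its other calls were the Treg programme (0.032, and adjusted p = 0.13 with an estimated correlation), glycolysis (0.027, and adjusted p = 0.82 with an estimated correlation), the interferon response and the stress response (0.024 each, and adjusted p = 0.76 with an estimated correlation). In Th17 cells 13 genes passed (9 higher and 4 lower), among them Ubd (2.27 ± 0.49) and Tk1 (1.03 ± 0.20) as higher and Nhlrc3 (-1.61 ± 0.29) as lower. In Th17 cells camera called the cell cycle list higher, with 1 of 24 rising (7 rose and 1 fell when adjusted over the list alone; 0.0047, and adjusted p = 0.56 with an estimated correlation). Glycolysis was called higher (0.030, and adjusted p = 0.78 with an estimated correlation). Naive T cell genes (0.035, and adjusted p = 0.56 with an estimated correlation) and apoptosis genes were called lower (0.035, and adjusted p = 0.49 with an estimated correlation). The Th1 count was 17 without WT 48 h replicate 1, 18 without Malt1-/- 48 h replicate 2 and 16 without WT 72 h replicate 5. The Th17 count was 476 without WT 48 h replicate 5, 34 and 308 without WT 72 h replicate 1 or 2, and 204 without Malt1-/- 72 h replicate 4. It was from 2 to 5 without any other array but Malt1-/- 72 h replicate 2. It was 0 with median scaling or with only these 20 arrays in the fit, where 1766 genes had an unadjusted p under 0.05 in the fit of all arrays. Without 1 array Ubd lost its call in 14 and Tk1 in 11 of 20 fits (adjusted p up to 0.10). Without WT Th1 72 h replicate 4 the helper cytokine call (adjusted p = 0.081) and the pathogenic Th17 call (adjusted p = 0.091) in Th1 cells were lost. The other list calls lost with an estimated correlation, apart from cell cycle, were lost in 6 to 10 of the 20 fits (adjusted p up to 0.50).

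Th17 cells were next compared with Th1 cells of the same genotype and time, to show what parts the lineages. In WT cells at 48 h Il17f, Pdpn (podoplanin), Il17a and Aqp3 (a water and glycerol channel) were higher in Th17 cells, with fitted differences of 8.97, 6.71, 5.71 and 5.44 that are no measured sizes, since each was detected on 1 of 5 Th1 arrays. The difference of Il17f was 9.93 without WT Th1 replicate 4. Nt5e (CD73, which makes adenosine) was higher by 5.27. Ifng was lower in Th17 cells by -7.67 and Il2 by -4.51, and the cytokine Il3 was at least 31.4-fold lower. In WT cells at 72 h Il17f was at least 451-fold and Il17a at least 48.7-fold higher, Ifng was lower by -7.91, and the interferon-induced genes Ifitm3 (-5.30), Isg15 (-5.25) and Usp18 (-4.68) were lower. In Malt1-/- cells Il17f was at least 159-fold higher in Th17 cells at 48 h and at least 143-fold higher at 72 h, Nt5e was higher by 7.80 and 7.97, and Ifng was lower by -5.51 and -6.22. At 72 h Osr2 was at least 69.5-fold lower in Malt1-/- Th17 than Th1 cells.

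The Th17 programme was higher in Th17 cells in 9, 10, 9 and 8 of 14 genes (WT at 48 h and 72 h, Malt1-/- at 48 h and 72 h), with 1 gene lower in Malt1-/- cells at 72 h. The Th1 programme was lower in 13, 12, 12 and 10 of 15 genes and higher in 1 each, and TGF-beta response genes were higher in 7 of 10 in each comparison and lower in none. Pathogenic Th17 genes, which include Csf2 and Tbx21, were lower in Th17 cells in 8, 7, 8 and 7 of 10 cases and higher in 1, 2, 1 and 1. These camera calls held with an estimated correlation, with adjusted p from 6.6e-05 to 0.018 for the Th17 programme and from 3.6e-07 to 0.00017 for the Th1 programme. The interferon response was lower in 7, 10, 7 and 12 of 17 genes and higher in none (adjusted p = 0.026, 0.040, 0.063 and 0.0092 with an estimated correlation). Treg genes were higher in 6, 6, 6 and 4 of 10 cases and lower in 3, 1, 2 and 2. In Malt1-/- cells at 72 h the Th2 list was lower in 4 of 8 genes (camera adjusted p = 5.4e-05, and adjusted p = 0.011 with an estimated correlation). There 12 of 24 cell cycle genes were higher and 1 lower (0.00054, and adjusted p = 0.14 with an estimated correlation). Beside them 5 of 7 myeloid markers were higher (0.00046, and adjusted p = 0.053 with an estimated correlation). Over all genes 1873 and 2023 passed in WT cells at 48 h and 72 h and 1991 and 2227 in Malt1-/- cells, with 1094, 1036, 1055 and 1244 of them higher in Th17 cells. No array left out moved these counts by over 1.5 times. Median scaling gave 1166 and 1463 genes at 72 h in WT and Malt1-/- cells, and fits of the compared arrays alone gave 772 in WT at 72 h and 3167 in Malt1-/- at 48 h.

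The last question was what changed between 48 h and 72 h. In WT Th17 cells the kinase gene Matk rose by 2.88, and Il1rn, the antagonist of interleukin 1, fell by 2.07 and Srm, which makes spermidine, by 1.53. Of 24 cell cycle genes 7 fell and none rose (12 fell when adjusted over the list alone; camera adjusted p = 0.00054, and adjusted p = 0.32 with an estimated correlation). At the same time 5 of 13 apoptosis genes rose and 1 fell (camera adjusted p = 0.0016, and adjusted p = 0.15 with an estimated correlation). Naive T cell genes (3 of 11 rose; camera adjusted p = 0.022, and adjusted p = 0.32 with an estimated correlation) and T cell receptor signalling genes (2 of 18 rose; 0.030, and adjusted p = 0.35 with an estimated correlation) were called higher. In Malt1-/- Th17 cells Nrn1 (neuritin, 3.68), Ubd (3.02) and Upp1 (uridine phosphorylase, 2.70) rose. Glycolysis genes were called higher with 0 of 13 passing (9 rose when adjusted over the list alone; camera adjusted p = 1.4e-08, and adjusted p = 0.43 with an estimated correlation). Beside them the myeloid list was called higher with 1 of 7 rising (4 when adjusted over the list alone; 0.0075, and adjusted p = 0.43 with an estimated correlation).

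In WT Th1 cells Ttc39c rose by 3.12 and the protease inhibitor Timp1 by 3.40, Tnfsf11, the ligand RANKL, fell by 2.65, and no list was called. In Malt1-/- Th1 cells Inhba, an activin subunit (3.06), Osr2 (3.05) and Scin (2.89) rose. There 6 of 8 Th2 genes rose and none fell (camera adjusted p = 1.6e-06), a call that held with an estimated correlation (adjusted p = 0.0056 with an estimated correlation). Interferon response genes rose in 7 of 17 cases (8 when adjusted over the list alone; camera adjusted p = 0.00011, and adjusted p = 0.17 with an estimated correlation). Helper cytokines rose in 6 of 24 (0.00062, and adjusted p = 0.17 with an estimated correlation). Cell cycle genes fell in 3 of 24 (8 when adjusted over the list alone; 0.00016, and adjusted p = 0.19 with an estimated correlation). In all, 1323 genes passed in WT Th17 cells (533 higher at 72 h), 75 in Malt1-/- Th17 cells (62 higher), 1126 in WT Th1 cells (598 higher) and 638 in Malt1-/- Th1 cells (445 higher). Timp1 lost its call without WT 72 h replicate 2 or 3 (adjusted p up to 0.057). The myeloid call in Malt1-/- Th17 cells was lost without 72 h replicate 2 or 5 (adjusted p up to 0.10). The naive T cell and T cell receptor signalling calls in WT Th17 cells were lost without 48 h replicate 2 or 4 or 72 h replicate 4 or 5 (adjusted p up to 0.080).

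These counts over time moved with single arrays. In WT Th17 cells the count was 754, 764 and 747 without 48 h replicate 1, 2 or 4 and 764 and 364 without 72 h replicate 1 or 3. It was 192 with median scaling, which raised the share of higher genes from 40.3% to 80.7%. In Malt1-/- Th17 cells it was 24, 34, 26 and 39 without 48 h replicate 2, 3, 4 or 5 and 38 and 20 without 72 h replicate 1 or 3. In WT Th1 cells it was 421 without 48 h replicate 5 and 354, 397, 2229 and 630 without 72 h replicate 2, 3, 4 or 5. In Malt1-/- Th1 cells it was 281, 284, 386 and 335 without 48 h replicate 1, 3, 4 or 5 and 206, 1107, 373 and 262 without 72 h replicate 1, 2, 3 or 5. With only the compared arrays in the fit, 1 gene passed in WT Th17 cells, 1 in WT Th1 cells and 354 in Malt1-/- Th17 cells. Without the 8 arrays closer to another group the counts were 2610, 2371, 558 and 1890 in WT Th17, WT Th1, Malt1-/- Th17 and Malt1-/- Th1 cells.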

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

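The tests of RNA from myeloid cells, of background correction and scaling, of exchanged genotype labels and of mixed RNA were chosen only after the result was seen, as was the fit without the 8 arrays closer to another group, while the tests of other splits and of exchanged time labels were planned before, although the spread by which the latter is read was added after.

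Other splits of the same arrays into groups of the same sizes were counted for each comparison, 100 of them with the real one included. Chance could be excluded for the genotype comparisons in Th17 cells at 48 h (1 split gave as many genes, 685 in the real one and at most 450 in the others) and Th1 cells at 48 h (1 split, 149 and 25). In Th17 cells at 72 h the share of splits was under the limit (2 splits, 474 and 795), but this does not exclude chance. Another split there called more genes than the real one, and the count ran from 105 to 846 with 1 array left out. Chance could not be excluded in Th1 cells at 72 h (6 splits, 297 and 722). It could be excluded for the difference between lineages at 48 h (1 split, 15 and 3). Between times in Th17 cells the share was under the limit (2 splits, 13 and 14), but this does not exclude chance. There another split called more genes than the real one, and the count ran from 2 to 476 with 1 array left out and was 0 with median scaling or with only the compared groups in the fit. It could not be excluded for the difference between lineages at 72 h (6 splits, 75 and 740) or between times in Th1 cells (8 splits, 8 and 425). It could be excluded for all 4 lineage comparisons (1 split each, 1873 against 486 and 2023 against 1527 in WT cells at 48 h and 72 h, 1991 against 198 and 2227 against 792 in Malt1-/- cells). Over time it could be excluded in Malt1-/- Th1 cells (1 split, 638 and 188), but not in WT Th1 cells (5 splits, 1126 and 1703). In WT Th17 cells (2 splits, 1323 and 2020) and Malt1-/- Th17 cells (2 splits, 75 and 86) the share was under the limit, which does not exclude chance. In both, another split called more genes than the real one. With 1 array left out their counts ran from 364 to 1921 and from 20 to 110. The splits that called 740 genes where 75 were real and 425 where 8 were real called several times the real count, and what drove these calls was not tested.

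Myeloid markers were higher in Malt1-/- Th17 cells at 72 h, with S100a8 at 9.13 against 4.62 and S100a9 at 7.93 against 4.47 (undetected in WT), and with Lyz1 and Fcer1g also higher. Over the Malt1-/- arrays S100a8 ran from 7.32 to 11.77, S100a9 from 5.99 to 10.77 and Lyz1 from 6.26 to 9.04. Each of them, and Fcer1g (7.15 to 9.80), was highest in replicates 2 and 5. What drove this shared spread was not tested. Background correction or scaling as the whole cause of the S100a8 difference between genotypes is argued against, since it kept its call at 2.41 (in place of 4.50) without background correction and at 4.53 with median scaling, although its difference between lineages fell from 4.15 to 2.29 and lost its call without background correction (adjusted p = 0.062). RNA from myeloid cells may be the source, but the other myeloid genes did not decide it: of 8 further members measured without the filter, 1 (Lyz2) was higher with an unadjusted p under 0.05, and 4 were detected on no array of either group. Other myeloid genes such as Tyrobp (4.88 against 5.22) and Csf1r (4.92 against 5.02) lay near background. The starting cells were purified as CD4+CD62L+, but the purity of the cultures is not given. The CD8 T cell marker Cd8b1 had a level of 11.12 in WT Th1 cells at 72 h, detected on 5 of 5 arrays, so the purification cannot decide the question. Myeloid RNA and expression by the T cells themselves cannot be told apart. An effect of the genotype on T cells stays open, as untested.

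Of the 40 arrays, 8 lay closer to the mean of another group than to that of their own: WT Th17 48 h replicate 5, WT Th17 72 h replicates 4 and 5, Malt1-/- Th17 72 h replicate 2, WT Th1 48 h replicate 1, Malt1-/- Th1 48 h replicate 2, WT Th1 72 h replicate 4 and Malt1-/- Th1 72 h replicate 2. Exchanged genotype labels are excluded, since Malt1 in these arrays lay at least 2.26 on the log2 scale from any array of the other genotype. Exchanged time labels of the Malt1-/- Th1 replicate 2 arrays were not decided: on 1126 genes that changed with time in WT Th1 cells, with 0 the mean of the other 48 h arrays and 1 that of the other 72 h arrays, the 72 h array lay at 0.399 and the 48 h array at 0.356, and either way of labelling puts 1 array several SD (0.0702) above the other 48 h arrays and the other below all other 72 h arrays (lowest 0.555, SD 0.330), so the halfway line set before does not separate the labels. A ninth array, Malt1-/- Th17 48 h replicate 1, had Il17a at 10.21 against 6.92 to 7.66 in the others of its group. A median of 62.7% of WT RNA over 5 genes would be needed for such levels. The Malt1 signal of the array allowed at most 5.05%, so mixed-in WT RNA is excluded. RNA from another Malt1-/- sample, which the Malt1 signal cannot bound, was not tested. On the 1126 genes of time WT Th1 72 h replicate 4 scored -0.285 against 0.375 to 0.623 in the rest of its group, and no biological explanation of these arrays was tested.

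Single arrays stood apart, by the gap to the nearest array as a share of the range of the group, in 18 of 139 groups of 5 arrays. Chance flags about 1 in 20 groups, and 8 of the 18 were in Malt1-/- Th17 48 h replicate 1. That array was highest for Ctla4 (0.838, at 11.88 against 11.14 to 11.26), Foxp3 (0.841), Gata3 (0.764), Il17a (0.773), Il17f (0.921, at 13.74 against 12.27 to 12.39), Il2 (0.738, at 9.87 against 6.41 to 7.32) and Tnfrsf4 (0.790) and lowest for Ifng (0.768). Foxp3 was highest in Malt1-/- Th17 72 h replicate 1 (0.881), Gata3 in WT Th17 48 h replicate 5 (0.942) and Il17a in WT Th17 72 h replicate 4 (0.728). Il17f was lowest in WT Th17 72 h replicate 3 (0.832) and highest in WT Th1 48 h replicate 4 (0.915, at 9.37 against 4.45 to 4.87). Il2 was lowest in WT Th17 72 h replicate 3 (0.741), WT Th1 48 h replicate 1 (0.831) and WT Th1 72 h replicate 5 (0.714). Tnfaip3 was highest in Malt1-/- Th1 48 h replicate 2 (0.742), and Tnfrsf4 lowest in WT Th17 72 h replicate 5 (0.810).

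The effect of genotype differed between lineages or times, by the test of the difference itself, for the following genes. Where a gene was undetected in a compared group its value is a fitted difference and no measured size. This holds between lineages at 48 h for Nts, Gm4951, Cxcr6, Slc14a1, Calcb and Alpk2, at 72 h for S100a8, S100a9, Il17a, Edn1 and Osr2, and over time in Th1 cells for Upk1a and Slc14a1. At 48 h the effect in Th17 minus that in Th1 cells was 2.15 for Acsl6, -2.52 for Alpk2, -1.48 for Calcb, 1.76 for Cxcr6, -1.32 for Fam107b, 1.80 for Gm4951, 2.26 for Nts, -1.90 for Piwil2, -1.14 for Slc14a1 and 1.99 for Zfp318. At 72 h it was -3.43 for Csf2, -3.30 for Edn1, 2.81 for Fscn1, -3.49 for Il17a, 2.59 for Il18r1, -3.79 for Il4, 2.52 for Kynu, -4.23 for Osr2, 4.15 for S100a8 and 3.26 for S100a9. Between 72 h and 48 h in Th17 cells it changed by -0.86 for 0610030E20Rik, -2.44 for Ctss, 2.23 for Kynu, -1.61 for Nhlrc3, 1.27 for Prpsap1, 1.03 for Tk1, 2.27 for Ubd, 1.30 for Vcl and -1.845 for Vsir. In Th1 cells it changed by 3.71 for Ccr8, 2.35 for Efna5, 1.69 for H1f2, 1.82 for Nts, 3.50 for Scin, -1.35 for Slc14a1 and -1.15 for Upk1a. When 1 array was left out, the call was lost for Acsl6 in 16 of 20 fits, Fam107b in 14, Cxcr6 and Zfp318 in 10, S100a9 in 9, Il18r1 in 4, Piwil2 in 3 and Slc14a1 at 48 h in 2, and for the genes of Th17 cells over time other than Nhlrc3 in 11 to 16. The highest adjusted p among these fits was 0.11.

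Outside the named genes, 3569 kept probes had no single gene symbol. Of these, 94 were called between genotypes in Th17 cells at 48 h, 64 in Th17 cells at 72 h, 14 in Th1 cells at 48 h and 39 in Th1 cells at 72 h.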

How the results depend on the processing

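The fit without the 8 arrays closer to another group was chosen only after the result was seen, and the others were planned. The counts of called genes depended on the processing, and so did the calls of named genes. Of 481 named values in the genotype comparisons, 141 were called in the fit of all arrays. Of these calls 12 were lost without background correction, 35 with median scaling, 24 with no detection filter and 44 with only the compared groups in the fit. The other values count as kept below when they stayed uncalled in the same direction. Of 481 named values in the genotype comparisons, 454 kept their direction and side of the threshold without background correction, 432 with median scaling, 457 with no detection filter, 419 with only the compared groups in the fit, 473 with the replicate block and 389 without the 8 arrays, where 76 newly passed. Among all named genes 1 value called in the fit of all arrays reversed, that of Upk1a for genotype by time in Th1 cells with no detection filter (0.060, adjusted p = 0.998, against -1.15). This was a change of probe, since without the filter another Upk1a probe had the highest mean and was used. No gene list called in the fit of all arrays reversed. Values not called in that fit did change direction, among them 9 of the 481 named genotype values and 10 of 116 genotype list values with median scaling. With an estimated correlation 19 of 20 list calls of the genotype comparisons, 17 of 22 of the interactions and 38 of 70 of the lineage and time comparisons were lost. Signal over background limits what can be said of genes detected on few arrays, and the files give no chip numbers, so the planned block by chip was not run. Where a count moved, the cause was not tested, except that fits of the compared groups alone estimate the spread from fewer arrays. A missing filter adds genes to the adjustment and can change the probe used for a gene.

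Without background correction, and with the value table of the authors, the change of the genotype effect over time was called for 78 genes in Th17 cells and 13 in Th1 cells. Median scaling gave 131 genes for genotype in Th17 cells at 72 h, 62 in Th1 cells at 48 h and 141 in Th1 cells at 72 h, 36 for genotype by lineage at 72 h, 0 for genotype by time in Th17 cells, 1166 and 1463 for lineage at 72 h in WT and Malt1-/- cells, and 192, 366 and 26 for time in WT Th17, WT Th1 and Malt1-/- Th17 cells. It shifted the median of all genes by 0.17 for genotype in Th17 cells at 48 h, 0.13 in Th17 cells at 72 h, 0.23 for genotype by lineage at 48 h and -0.12 for lineage in WT cells at 48 h. The share of called genes that were higher depended on it too. For genotype it was 93.1% in place of 53.4% in Th17 cells at 48 h, 77.1% in place of 65.4% in Th17 cells at 72 h, 38.7% in place of 56.4% in Th1 cells at 48 h and 83.7% in place of 66.7% in Th1 cells at 72 h. It was 83.3% in place of 53.3% and 30.6% in place of 45.3% for genotype by lineage at 48 h and 72 h, 31.9% in place of 58.4% and 70.7% in place of 53% for lineage at 48 h in WT and Malt1-/- cells, and 80.7% in place of 40.3% and 91.1% in place of 69.7% for time in WT Th17 and Malt1-/- Th1 cells. No detection filter gave 440 and 299 genes for genotype in Th17 cells at 48 h and 72 h and 3 for genotype by time in Th17 cells. The stricter detection filter gave 3 and 43 genes for genotype by lineage at 48 h and 72 h and 41 and 3 for genotype by time in Th17 and Th1 cells. With only the compared groups in the fit, genotype gave 1164 and 58 genes in Th17 cells at 48 h and 72 h and 82 in Th1 cells at 72 h, genotype by lineage 76 and 27, genotype by time 0 in Th17 and 5 in Th1 cells, lineage 772 in WT cells at 72 h and 3167 in Malt1-/- cells at 48 h, and time 1 in WT Th17, 1 in WT Th1 and 354 in Malt1-/- Th17 cells. The replicate block gave 26 genes for genotype by lineage at 48 h, and the intensity trend with robust variances 42 for genotype by time in Th17 cells.

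Without the 8 arrays the genotype counts were 1651, 1685, 350 and 553 (Th17 cells at 48 h and 72 h, Th1 cells at 48 h and 72 h), of which 649, 418, 132 and 266 were shared with the fit of all arrays. The counts were 181 and 347 for genotype by lineage at 48 h and 72 h, 341 and 42 for genotype by time in Th17 and Th1 cells, and 2610, 2371, 558 and 1890 for time in WT Th17, WT Th1, Malt1-/- Th17 and Malt1-/- Th1 cells. These arrays were left out because they lay near another group in the same data, which by construction draws the groups apart, so these higher counts are no better estimate.

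With 1 array left out, the genotype counts ran from 281 to 1156 and from 105 to 846 in Th17 cells at 48 h and 72 h and from 84 to 203 and from 138 to 607 in Th1 cells. Genotype by lineage ran from 7 to 68 at 48 h and from 44 to 109 at 72 h, and genotype by time from 2 to 476 in Th17 and from 7 to 18 in Th1 cells. Lineage ran from 1501 to 1787 and from 1702 to 2202 in WT cells at 48 h and 72 h and from 1622 to 1814 and from 1962 to 2189 in Malt1-/- cells. Time ran from 364 to 1921 in WT Th17, from 354 to 2229 in WT Th1, from 20 to 110 in Malt1-/- Th17 and from 206 to 1107 in Malt1-/- Th1 cells.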

Other observations

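The tests of a chromosome segment around Malt1 and of single probes were chosen only after the result was seen, while the test of a later course of time was planned before.

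Beyond the genes described above, several other changes came with the loss of Malt1. In Th17 cells at 48 h Tgfbr1, a receptor of TGF-beta, was higher by 1.15, Fas, a death receptor, by 1.10, Bbc3, a death-promoting gene of the p53 response, by 1.23, and Chac1, which degrades glutathione, was lower by -2.64. In Th17 cells at 72 h Fam217b was lower by -1.79, Stat4, which signals from the interleukin 12 receptor, by -1.23 and Satb1, a chromatin organiser of T cells, by -0.94, and Tnfsf4 was higher by 1.45. Leaving out 1 array ended the call of Tgfbr1 in 7 of 10 fits, of Stat4 without WT replicate 3 (adjusted p = 0.058), of Satb1 without Malt1-/- replicate 2 or 5 (adjusted p up to 0.065) and of Tnfsf4 without WT replicate 1 or 3 or Malt1-/- replicate 5 (adjusted p up to 0.081). In Th1 cells at 48 h Acsl6, which activates fatty acids, was lower by -2.14 and Asb2, a subunit of a ubiquitin ligase, higher by 1.97. In Th1 cells at 72 h Tnfsf8, the ligand of CD30, was higher by 1.67 and Tnfsf4 by 1.58.

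Other probes of a named gene did not always move with the one used. Nme7 was higher by 2.09 in Th17 cells at 48 h and 2.51 at 72 h, and at 48 h 2 of its 7 other kept probes were called the same way and 3 had the opposite sign. The Foxp3 probe used gave -0.20 and -0.22 in Th17 cells at 48 h and 72 h, while its 3 other kept probes had the opposite sign. Of these 1 (ILMN_2635132) passed, at 72 h only (1.48, adjusted p = 0.046 over all kept probes). The Ifng probe used did not pass in Th17 cells, while its other probe (ILMN_2791459) was higher by 1.59 at 48 h (adjusted p = 0.018) and 1.90 at 72 h (adjusted p = 0.0053). Alpk2 was lower by -1.84 in Th17 cells at 48 h, and its other kept probe had the opposite sign, as had 1 of the 2 other kept probes of Bbc3.

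Of the genes called in all 4 genotype comparisons, 3 (Ppic, Srfbp1 and Tnfaip8) lie on chromosome 18 within 100 protein-coding genes of Malt1, which is 20% of the 15 other than Malt1 that could be placed, against 0.953% of 10488 other tested genes (Fisher's exact test, two-sided, p = 0.00038). The window was set after these genes were seen, and all 3 lie toward its edge. A chromosome segment carried along with the targeted Malt1 allele may be the source, but with the genes called in all 4 comparisons left out, 4 of 100 tested genes near Malt1 (4%) and 168 of 10388 elsewhere (1.62%) were called in at least 2 comparisons (Fisher's exact test, two-sided, p = 0.082), which leaves it open. A sequence difference under a single probe does not account for Ppic, whose other probe was called the same way in 4 of 4 comparisons. For Srfbp1 it stays open, since its other probe was called in 0 of 4, and Tnfaip8 had no other kept probe. The labels do not say how the allele was made or how far the mice were backcrossed, and an effect of Malt1 on these genes stays open, as untested.

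Few genes changed with time in Malt1-/- Th17 cells (75, against 1323 in WT Th17 cells), which could be a later course of time in these cells. The contrast depended on the fit: median scaling gave 26 against 192, and with only the compared groups in the fit it turned round, with 354 against 1. The direct test of the difference called 13 genes. On the mean score of 1126 genes that changed with time in WT Th1 cells, WT Th17 cells rose by 0.487 between the times (exact permutation test, two-sided, n = 5 per group, p = 0.00794, the smallest this design can give, adjusted p = 0.032 over 4 tests) and Malt1-/- Th17 cells by 0.257 (exact p = 0.024, adjusted p = 0.048). At 72 h the Malt1-/- score was lower by -0.309 (0.0889 ± 0.116 SD against 0.398 ± 0.306 SD, exact p = 0.071, adjusted p = 0.095), and at 48 h by -0.0791 (exact p = 0.17, adjusted p = 0.17). The gene set of the score is itself unstable. Its count ran from 354 to 2229 with 1 array left out, and other splits of the WT Th1 arrays could not exclude chance for it. The spread of the 5 WT arrays at 72 h keeps a later course open, and the scores do not decide it.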
